A study of Mus musculus with 6 samples.

How the data were processed

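Circular RNA (circRNA) was profiled with a commercial mouse circRNA array (Arraystar, version 2) in complexes of retinal pigment epithelium (RPE), choroid and sclera from male mice. Per the labels' protocols, 3 samples came from eyes with choroidal neovascularization (CNV), taken 7 days after laser photocoagulation around the optic disc, and 3 samples came from age-matched mice without laser. The laser was a 532 nm diode laser at 100 mW, with pulses of 0.1 s, spots of 50 µm and 25 burns per eye, per the labels. Total RNA was extracted with Trizol, treated with RNase R, an exonuclease that digests linear RNA, then amplified with random primers and labelled with Cy3, per the labels' protocols. The labels do not state that each sample came from a separate animal, so p-values measure only the spread between these samples, part of which may be technical.

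The deposited scanner tables give spot brightness as a linear intensity, background-subtracted by Feature Extraction 11.0.1.1 per the file headers. The deposited value table holds log2 values that the authors had normalized. The normalization used for that table is not given in the sources used here. Its scale was taken as log2 from a comparison with the scanner values of the same arrays, which gave correlations across probes of 0.964 to 0.969. Column medians of that table were 5.90, 5.92 and 5.92 for controls 1 to 3 and 5.92, 5.91 and 5.91 for CNV 1 to 3, so the arrays had been brought to nearly equal distributions. How it was background-corrected stays unknown, and it served only as an alternative. All 6 arrays lay on 1 slide per the file headers, with 1 scan, so slide could not be fitted as a block. Slide row 1 held the 3 control arrays and CNV 2, and slide row 2 held CNV 1 and CNV 3. With no control in row 2, a fit with slide row as a term takes its group difference from CNV 2 alone, as slide row 1 does.

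The main values were log2 of the processed signal minus each array's 75th percentile over all non-control probes. Spots marked as non-uniform or as population outliers were left out, and spots of 1 probe were averaged. A probe was kept when it was well above background on at least 3 of the 6 arrays, which kept 13358 of 14236 circRNA probes. The same filter kept 4 of the 15 negative probes, so passing it does not by itself show that a transcript was detected. The arrays also carried 50 mRNA probes spotted 10 times each, of which 46 were kept. Their accessions were matched without versions to a RefSeq gene table of the GRCm38.p6 assembly, which named 44 of the 50 and 40 of the 46 kept. Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust options), with Benjamini-Hochberg adjustment over the kept circRNA probes and, separately, over the kept mRNA probes. No covariate was used. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

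The design, the alternatives, the rule for named circRNAs and 21 gene lists holding 988 genes were fixed before the data were examined. The rule took the 12 circRNAs with the largest change in each direction among those past adjusted p 0.05, well above background on all 3 arrays of the higher group and without overlap between the groups, filled up by the largest changes with unadjusted p under 0.05 that met the other conditions. The files used here do not pair circRNA probe identifiers with host genes, so at most 2 identifiers per direction are printed. Tests of the gene lists through host genes, and tests of circRNA classes, were not analysed here for the same reason. Of the list genes, 4 had an mRNA probe. The comparison of mRNA probes was added after the probes had been seen. A circRNA not well above background on any array of a group has only a bound on its fold there.

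The replicate numbers of the titles were checked for pairing through the deviations of each array from its group mean across circRNA probes. The correlations were 0.41 for pair 1, 0.18 for pair 2 and 0.17 for pair 3. All exceeded 0.1, so by the rule set for this the numbers were taken to pair the samples, on evidence from the values and not from the labels. The deposited scanner tables number the samples differently from the titles, in the same order within each group, so both numberings give the same pairs. Control 2 nevertheless correlated better with CNV 3, at 0.32, and control 3 correlated with CNV 2 at 0.06. Deviations from a group mean cancel out within the group. The likeness of control 1 and CNV 1 alone therefore makes the correlations among the remaining arrays positive on average. The rule thus could not show pairing for pairs 2 and 3, where the pairing is an assumption. A fit with the replicate number as a block was run beside the unblocked one.

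The alternatives fixed beforehand were quantile normalization, median centring, the 75th percentile over probes well above background on all arrays, normexp background correction with an offset of 50 followed by quantile normalization, the authors' table, no filter, a filter on all 6 arrays, trend and robust options, array weights, the replicate block, and leaving out each array. The normexp alternative used median in place of mean spot signals, because the deposited scanner tables give medians. Alternatives added after seeing the data were slide row as a term, slide row 1 alone, pair 1 left out, and each array's 75th percentile as a covariate. For the mRNA probes, centring on their own median and a spread estimated jointly with the circRNA probes (without and with the replicate block, and without pair 1) were also added. The number of arrays limits the precision. The fit was tested on simulated values made from the spread of the 13357 circRNA probes measured on every array. Of 200 circRNAs changed 2-fold, 0 were recovered, and of 200 changed 4-fold, 95.5% were recovered with 9 false calls. For the mRNA probes, 91.7% of 12 simulated 2-fold changes were recovered with 1 false call. There 12 of the 46 probes changed at once, which makes the adjustment milder than for a single changed probe. That share therefore does not hold for a single 2-fold change.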

Results

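The study asked which circRNAs differ between mouse eyes with laser-induced choroidal neovascularization, the growth of new vessels from the choroid that follows laser rupture of Bruch's membrane, and eyes without laser. RNA from RPE, choroid and sclera was hybridised to 6 single-colour arrays, 3 for CNV at 7 days and 3 for controls. The 75th percentile of the probe intensities was 77.2, 108 and 103 on controls 1 to 3 and 77.8, 123 and 129 on CNV 1 to 3. The number of circRNA probes well above background was 13077 ± 475 (SD, n = 3) in controls and 13066 ± 570 (SD, n = 3) in CNV. The difference of -11 probes was smaller than the spread between arrays (two-sided exact permutation p = 1, where 3 against 3 arrays allow no p under 0.1).

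No circRNA passed the adjusted threshold between CNV and control eyes. Of 13358 circRNAs tested with limma, 0 were past an adjusted p of 0.05, and the smallest adjusted p was 0.765. At an unadjusted p under 0.05 there were 771 circRNAs, against 667.9 expected by chance. Of these, 676 also differed by at least 1.5-fold, with 304 higher and 372 lower in CNV, where simulated arrays with no change, no pairing and independent errors gave a mean of 528. The median fold was 1.73 among the higher and 1.81 among the lower. In 1514 circRNAs the 3 CNV values lay all above (948) or all below (566) the 3 control values, which is 11.3% of those tested where chance gives 10%. The 95% confidence interval of a circRNA reached a median of 0.61 log2 units to either side, or 1.52-fold.

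**Figure D1:**
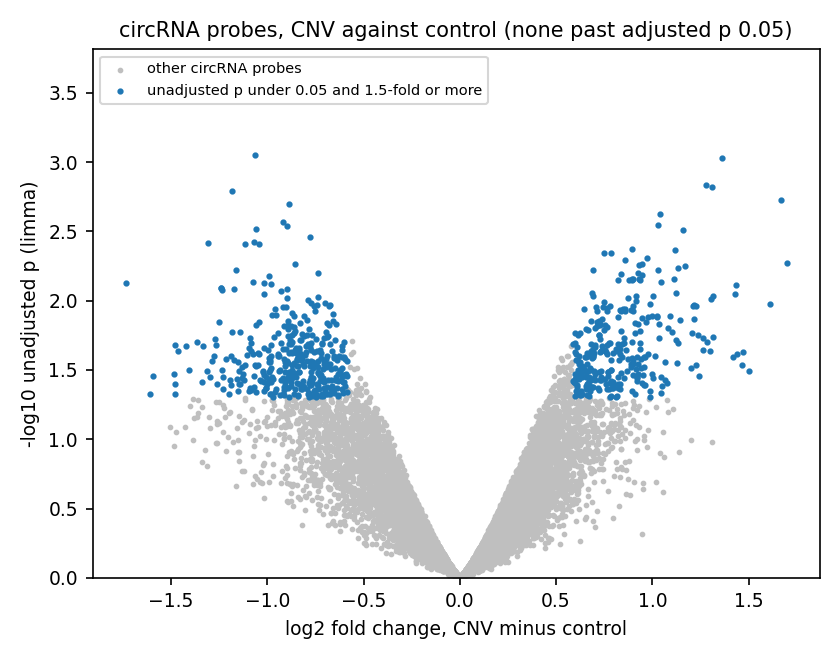
Each point is 1 circRNA probe, with the log2 fold change of CNV minus control on the x axis and -log10 of the unadjusted limma p on the y axis. The 676 probes with unadjusted p under 0.05 and at least 1.5-fold are blue, and 0 of the 13358 passed adjustment.

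The circRNAs named by rule were the 12 with the largest change in each direction, none of which passed the adjusted test. The circRNA with the identifier ASCRP4011527 had a log2 difference of 1.70 ± 0.45 (SE, n = 3 per group; limma adjusted p = 0.765), and ASCRP4007358 one of 1.67 ± 0.37 (SE; adjusted p = 0.765). As the rule required, both were higher in each of the 3 CNV arrays than in any control. In the other direction, ASCRP4002172 had a log2 difference of -1.74 ± 0.49 (SE; adjusted p = 0.765) and was well above background on 2 of the 3 CNV arrays, and ASCRP4010056 one of -1.31 ± 0.33 (SE; adjusted p = 0.765). Among the 12 lower circRNAs, 7 were well above background on all 6 arrays and spanned 2.26-fold to 2.47-fold, and the other 5 were measured on only some CNV arrays. Of the 7, ASCRP4010056 had intensities of 16.0, 17.7 and 15.4 on CNV 1 to 3. A kept negative probe had 12.9, 38.9 and 34.3 there, so the CNV level of ASCRP4010056 is uncertain. ASCRP4002172 had a mean normalized log2 signal of -2.04 in controls and -3.77 in CNV. The kept negative probes had control means from -3.49 to -1.56, and the dimmest had a CNV mean of -3.54. Both levels of ASCRP4002172 are therefore uncertain. The control mean of ASCRP4007358, -1.61, also lay below the -1.56 of the brightest kept negative probe. Among the 12 higher ones, 5 were well above background on all 6 arrays and spanned 2.48-fold to 3.24-fold, 4 were measured on only some control arrays and 3 on none. With normexp background correction and quantile normalization together, the log2 differences were 1.29 for ASCRP4011527, 0.87 for ASCRP4007358, -0.46 for ASCRP4002172 and -0.41 for ASCRP4010056. In the authors' deposited table those of ASCRP4002172 and ASCRP4010056 were -0.91 and -0.73. CNV 2 alone, the only CNV array in the slide row of the controls, differed from them by 2.81 for ASCRP4011527, 2.31 for ASCRP4007358 and -2.82 for ASCRP4002172. The files do not pair these identifiers with genes.

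The unadjusted count moved with single arrays, from 306 without control 2 to 1761 without control 1, and lay at 396 without control 3, 1169 without CNV 1 and 320 without CNV 2. The balance of directions turned too, with 511 higher and 1250 lower without control 1 against 180 and 126 without control 2, 247 and 149 without control 3 and 720 and 449 without CNV 1. It was 364 higher and 950 lower with the array signal as a covariate. With slide row as a term it was 1145 higher and 608 lower, in a fit whose group difference rests on CNV 2 alone, since the other row holds no control. The count was 1168 (455 higher, 713 lower) in the fit with a replicate block, again with 0 past the adjusted threshold, where paired arrays simulated with no change and independent errors gave a mean of 360.2. With limma's array weights 3530 circRNAs (1807 higher, 1723 lower) were past an adjusted p of 0.05, in a fit that gave 54.4% of all weight to CNV 3 and 33.2% to control 3.

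The similarity of arrays within a group overlapped that between groups. Correlations across circRNA probes, which are not independent replicates, ran from 0.918 to 0.967 among controls, from 0.935 to 0.966 among CNV arrays and from 0.915 to 0.978 between the groups. The highest belonged to control 1 and CNV 1. The first principal component held 43.1% of the variance and set controls 2 and 3, at 46.8 and 26.4, apart from control 1 and CNV 1, at -37.5 and -34.9. The second held 30.9% and set CNV 2 apart, at 52.8.

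**Figure D2:**
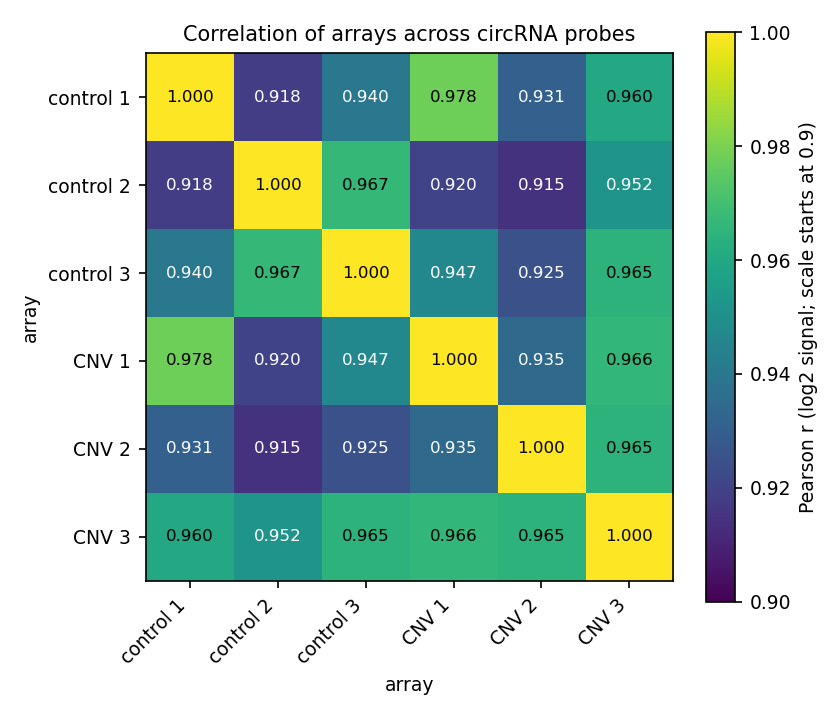
Pearson correlations of log2 signal across circRNA probes for each pair of the 6 arrays, with a colour scale that starts at 0.9. Control 1 and CNV 1 correlate at 0.978, above every pair within a group.

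The array's mRNA probes were compared as the only named transcripts, a comparison added after the probes were seen, with genes chosen after their values were seen. Whether their signal came from linear RNA left after RNase R, from circular RNA of the same exons or from unspecific binding was not tested. The probe of the olfactory receptor gene Olfr166 had a control mean of 0.97, above H2-Q7 (0.78), Lhfp (-1.22) and Cpt1a (-1.94). A signal above the negative probes therefore does not by itself show the named transcript. Apoe, which encodes a lipid-carrying apolipoprotein made by glia and macrophages among other cells, was 2.23-fold higher in CNV, with a log2 difference of 1.16 ± 0.24 (SE, n = 3 per group). Its normalized log2 signal was 3.54, 2.83 and 3.39 in controls and 4.35, 4.63 and 4.27 in CNV. The limma adjusted p over the 46 probes was 0.056, which did not pass. It was 0.039 without control 1 and 0.018 without CNV 1, but 0.144 without control 2, 0.193 without control 3, 0.144 without CNV 2 and 0.178 without CNV 3. Of these probes 0 were past the adjusted threshold and 5 had an unadjusted p under 0.05, and 41 of the 46 were higher in CNV, with a median log2 difference of 0.14 over all 46. Their mean normalized log2 signal was -1.07, -1.35 and -1.34 on controls 1 to 3 and -1.17, -0.88 and -0.90 on CNV 1 to 3. The mean of CNV 1 thus lay below that of control 1. Under 4 other scalings between arrays, 37 to 43 of the 46 were higher. The 3 CNV values lay all above the controls in 4 probes and all below in 1, which is 10.9% of the 46 where chance gives 10%. In the fit with a replicate block 3 probes passed, namely Lhfp (adjusted p = 1.5e-08), Apoe (0.0075) and Mbp (0.043). That fit gave every probe 1 common spread. With the spread estimated jointly with the circRNA probes, the blocked fit called 1 probe, Lhfp (adjusted p = 0.047), and Apoe did not pass (0.063).

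Lhfp, a member of the tetraspan family of membrane proteins, had a log2 difference of 2.18 ± 0.60 (SE; adjusted p = 0.150), with CNV values of -0.67, 1.62 and 1.93 and a control mean of -1.22 ± 0.21 (SD, n = 3), all 3 CNV values lying above the controls. It passed under 8 of 17 alternatives, such as median centring (adjusted p = 0.038) and pair 1 left out with joint spread (0.00038), and 2 of the 8, with slide row as a term and in slide row 1, both compare CNV 2 alone with the controls. The alternatives gave a range of adjusted p from 2.9e-13 to 0.386. Its difference was 3.00 without CNV 1, where it passed (adjusted p = 1.3e-07), 1.70 without CNV 3 and 1.46 with normexp and quantile normalization together. H2-Q7, a class I histocompatibility antigen, differed by 0.74 ± 0.27 (SE; adjusted p = 0.296), and all 3 CNV values lay above the controls. It passed without control 1, at 1.01 (adjusted p = 0.039). Actb, cytoskeletal beta-actin, differed by 0.81 ± 0.30 (SE; adjusted p = 0.296), and Cep41, a centrosomal protein, by 0.48 ± 0.21 (SE; adjusted p = 0.415), the latter again with no overlap between the groups. The control mean of Cep41 was -3.58, below the -3.49 of the dimmest kept negative probe, so its level is uncertain. With pair 1 left out, in a fit that gave every probe 1 common spread, H2-Q7, Actb, Tyr and Mbp passed (adjusted p = 0.014, 0.0039, 0.0054 and 0.0027). With joint spread none of these did (0.065, 0.065, 0.056 and 0.269). Rps4l was the 1 probe with all CNV values below the controls, at a difference of -0.32 ± 0.18 (SE; adjusted p = 0.584).

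Of the gene lists fixed beforehand, 4 had 1 member each on the array, and none of these members passed in the unblocked fit of all arrays. They were Apoe for Müller glia and astrocytes, Mbp for Schwann cells and nerve, Tyr for melanocytes and Cpt1a for mitochondrial metabolism. Mbp, a myelin protein, differed by 0.95 ± 0.46 (SE; adjusted p = 0.474), resting on CNV 2 at -1.85 where CNV 1 and CNV 3 were at -3.36 and -3.79 and the control mean was -3.95. Its probe was well above background on 1 control array only, so the control level is uncertain. Tyr, the tyrosinase of melanin synthesis, differed by 0.66 ± 0.29 (SE; adjusted p = 0.415) and was well above background on 1 control and 2 CNV arrays. Cpt1a, which admits fatty acids to mitochondria, differed by 0.52 ± 0.27 (SE; adjusted p = 0.534), and by 0.29 without control 2. With normexp and quantile normalization together, the differences of Mbp, Tyr and Cpt1a were 0.18, 0.06 and 0.14, and those of Cep41 and Rps4l were 0.07 and -0.06. CNV 2 alone differed from the controls by 2.10 in Mbp and passed both with slide row as a term (adjusted p = 0.0055) and in slide row 1 (0.00039), which are 1 comparison of the same array. Over its alternatives the adjusted p of Mbp ran from 0.00039 to 0.840, and without CNV 2 its difference was 0.38. With 1 member per list, no list was tested.

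**Figure D3:**
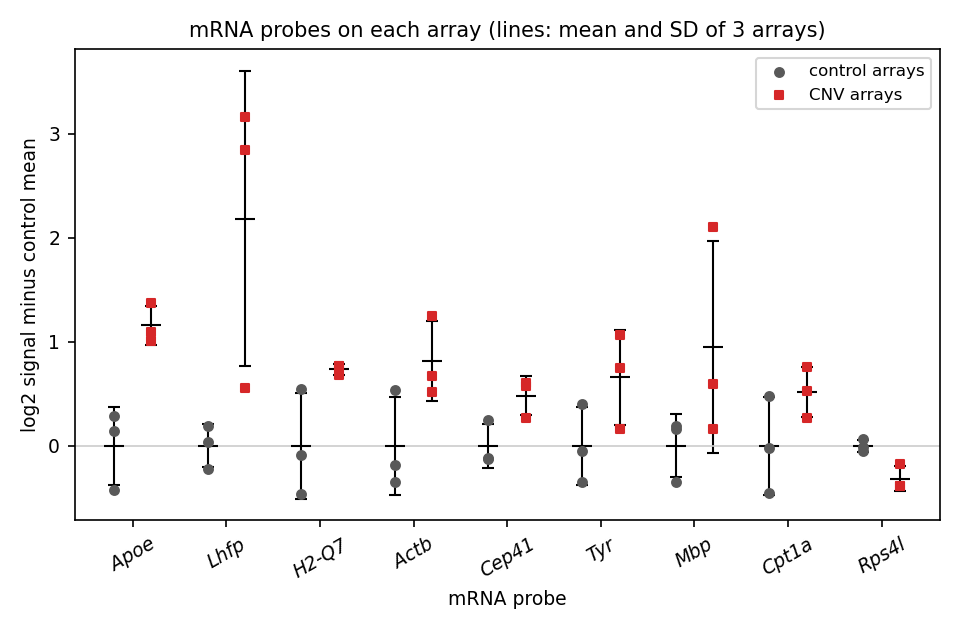
Log2 signal minus the control mean (y axis) of 9 mRNA probes (x axis) on each of 3 control arrays (circles) and 3 CNV arrays (squares), with lines for the mean and SD. The 3 CNV values of Apoe, Lhfp, H2-Q7 and Cep41 lie above their 3 control values, and the CNV values of Lhfp and Mbp are spread most widely.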

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

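Tests in this part that were chosen after the result was seen were the splits of the circRNA counts without array weights, the correlation in the brightest probes and all tests on Apoe. The splits with array weights, the splits of the mRNA count and the position tests were set before their values were seen.

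A pair of the array's 15 custom probes, whose targets the files do not state and which no comparison above used, had every CNV value above every control value. Their log2 differences were 0.48 and 0.73, with limma adjusted p of 0.445 and 0.270 over the kept circRNA control, custom and negative probes. The probe with 0.48 had a control mean of -2.72, within the -3.49 to -1.56 of the kept negative probes. Of the 15 custom probes 13 were higher in CNV, with a median difference of 0.22. Such a separation was also seen in 948 of 13358 circRNAs, and some circRNA control probes had every CNV value below every control value.

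The 6 arrays make 10 splits into 3 and 3, too few for a share under 0.05. For circRNAs past an adjusted p of 0.05, the real split gave 0, the highest other split gave 0, and so all 10 reached the real count. For circRNAs at unadjusted p under 0.05 and 1.5-fold, the real split gave 676 and the highest other 1411, and 4 of the 10 reached the real count. Each of the 3 splits above the real one kept control 1 and CNV 1 together, which points to a structure of the samples other than their groups. Among the 4 splits that part all 3 pairs, the others gave 111, 117 and 540, or 175, 161 and 855 with the replicate block against the real 1168. For the mRNA probes past an adjusted p of 0.05, the real split gave 0 and the highest other 1, and all 10 reached the real count.

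With array weights, the real split called 3530 circRNAs past an adjusted p of 0.05 and the highest other split 3904, and 2 of the 10 splits reached the real count. A candidate explanation is that the weights rest on a few arrays: 5 of the 9 other splits also called at least 500 circRNAs once arrays were weighted, while without weights each of the 10 splits called 0. The 2 arrays of largest weight held 87.6% of all weight in the real split and 87.9% in the other split with 3904 calls. The 3530 calls are therefore no support for a laser effect. Whether control 3 and CNV 3 show one could not be decided, since 3 against 3 arrays cannot separate the weights from the groups.

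Control 1 and CNV 1 deviated from their group means together. Noise of dim spots shared by the arrays of lowest signal is argued against by a correlation of 0.356 over the brightest of 5 equal bins of circRNA probes. On a scale from controls 2 and 3 at 0 to CNV 2 and CNV 3 at 1, over circRNAs chosen on those 4 arrays, CNV 1 had a median position of 0.706 and control 1 one of 0.703. Neither met the bound set for a wrong label or for its absence, so neither an unlasered CNV 1 nor a lasered control 1 can be decided. Over these 2188 circRNAs, CNV 1 differed from control 1 by a median of 0.02 log2 units in the direction of the other 4 arrays. In 52.4% of them the direction was the same. The median change among the other 4 arrays was 0.92, which the choice on those arrays can inflate. Pair 1 thus showed little of that difference. A shared day, litter or preparation was not tested, and the low signal of control 1 and CNV 1 goes with the pair.

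The Apoe signal was higher in CNV by 1.16 log2 units. More linear RNA left after RNase R cannot be decided. The other 45 mRNA probes had a median difference of 0.14, well under that of Apoe. Some of them were no brighter than the kept negative probes, and such a probe can show little of a change. Of the 46 mRNA probes 41 were higher and 5 lower in CNV, while 13 of the 14 circRNA control probes were lower (median -0.70). The mean over the 46 was nevertheless -1.17 on CNV 1, below the -1.07 of control 1. Digestion that differs between transcripts, and circular RNA or unspecific binding read by the mRNA probes, were not tested. The scaling between arrays is argued against by a smallest difference of 0.98 over 5 other scalings. The place on the slide stays open: in slide row 1 the only CNV array differed from the 3 controls by 1.37, and 1 array cannot settle it. A higher level of Apoe RNA 7 days after laser is only a hypothesis, beside slide row, leftover linear RNA and chance. The limma adjusted p of 0.056 did not pass.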

How the results depend on the processing

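All mRNA alternatives, slide row, slide row 1 alone, pair 1 left out and the signal covariate were chosen after seeing the data. The causes of the changes below were not tested. The count of circRNAs past an adjusted p of 0.05 was 0 under 13 of 14 alternatives and without any 1 array, and 3530 with array weights. The unadjusted count of 676 stayed within 1.5 times under 6 alternatives. It was 163 with normexp and quantile normalization together, 429 in the authors' table, 2282 with array weights, 1168 with the replicate block, 1753 with slide row as a term, 1438 in slide row 1, 2188 without pair 1 and 1314 with the signal covariate. Leaving out 1 array gave 306 to 1761: 1761 without control 1, 306 without control 2, 396 without control 3, 1169 without CNV 1 and 320 without CNV 2. The 4 printed circRNAs kept their direction under each alternative that tested them. They had been chosen on these arrays for large changes without overlap and could hardly turn, so this is no support for a difference. Their log2 differences ran from 1.16 to 2.81 for ASCRP4011527, 0.87 to 2.31 for ASCRP4007358, -2.82 to -0.46 for ASCRP4002172 and -1.78 to -0.41 for ASCRP4010056. They passed with array weights alone.

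The count of mRNA probes past an adjusted p of 0.05, 0 as reported, was 2 with median centring, 1 with the filter on all 6 arrays, 1 with trend and robust options, 1 with array weights, 3 with the replicate block, 1 with the replicate block and joint spread, 2 with slide row as a term, 3 in slide row 1, 7 without pair 1 and 2 with the signal covariate. The fits with the block and without pair 1 gave all mRNA probes 1 common spread. With joint spread the count without pair 1 was 1, and both slide row fits rest on CNV 2 alone, as no control lies in the other row. Leaving out 1 array gave 0 to 2, with 2 without control 1 and 2 without CNV 1. The Apoe difference ran from 0.98 to 1.37 over 17 alternatives, with adjusted p from 0.00097 (without pair 1, and 0.056 there with joint spread) to 0.080 and 8 past the threshold, the block, pair 1 and slide row 1 fits among them. Without 1 array its adjusted p ran from 0.018 to 0.193. The replicate block called Lhfp, Apoe and Mbp, with joint spread Lhfp alone, and changed no call among the circRNAs. The slide could not be fitted as a block on 1 slide, and host gene lists and circRNA classes were not run.

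The difference in probes well above background, -11, became 7.67 with the flag for positive and significant signal. Leaving out 1 array gave -262 to 315: 17.8 without control 2, 211 without control 3 and 315 without CNV 1. Signal over background limits 3 of the 12 named higher circRNAs to bounds.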

Other observations

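The test in this part was set before its value was seen. The 14 probes that the array design calls circRNA controls, each spotted 10 times, had a median log2 difference of -0.70 in CNV, and 13 of the 14 were lower. Their mean normalized log2 signal was 2.25, 2.73 and 2.60 in controls and 2.29, 1.33 and 2.04 in CNV, and 0 passed the adjusted test. The 4 kept negative probes had a median difference of 0.03. In the brightest of 5 equal bins of circRNA probes, 125 were lower and 42 higher in CNV at unadjusted p under 0.05 and 1.5-fold, while in the dimmest bin 72 were lower and 93 higher. The median log2 difference over all probes of a bin was 0.08 in the brightest and 0.02 in the dimmest. The brightest bin as a whole was thus not lower in CNV.

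A laser effect shared by all 3 pairs would make the same-numbered differences, which have no array in common, correlate across circRNAs. Their mean correlation was 0.158, between the bounds set for a shared effect and for none. The difference of pair 2 correlated with that of pair 3 at 0.468, while pair 1 correlated with pair 2 at 0.022 and with pair 3 at -0.017. The correlation of 0.468 is not particular to the same-numbered pairs. Over all 6 ways to match CNV to control arrays, the differences taken from controls 2 and 3 correlated at 0.244 to 0.476. The mean correlation was 0.151 with CNV 2 and CNV 3 exchanged, and 0.053, 0.071, -0.029 and -0.012 in the 4 matchings that parted control 1 from CNV 1. Whether a laser effect was shared could not be decided with 3 pairs.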
